A study of Mus musculus with 4 samples.

How the data were processed

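Total RNA of wild type C57/BL6 mice was extracted with the acid guanidinium method and labelled with Cy3 by a low-input amplification kit, per the labels' protocols. The 4 samples, whole intestine, crypt, y-organoid and o-organoid, were each hybridised to 1 array of the same Agilent design on 1 slide, so that no slide effect can be tested. The scanner files hold the intensity of each spot as deposited by the authors, on a linear scale. Per the file headers, these intensities came from Agilent Feature Extraction 10.7.3.1 with background subtraction, spatial and multiplicative detrending and surrogate values for dim spots. Flags for spots well above background, saturated spots and outlier spots are the scanner software's own. Probe coordinates are those of build mm9, per the file headers. The authors also deposited a value table, which was found to hold a ratio: the processed intensity of each spot over 1 constant per array, 40.47 for intestine, 25.16 for y-organoid, 36.94 for o-organoid and 29.45 for crypt. Each of its columns has a median of 1.0, on a linear scale and without centring of genes, so its scale, centring and direction are settled. The tool that made it is not given in the sources used here.

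On each array 1377 control spots were left out. The other spots belong to 39429 probes, of which 399 were spotted 10 times and 39030 were spotted singly. Probes were named through the RefSeq gene table of assembly GRCm38.p6, used for names only: 27234 by accession, 3576 by symbol and 565 by synonym, while 8054 kept the name in the files. This gave 30107 named genes or transcripts. No spot was saturated, and 162, 154, 165 and 108 spots were outliers on the intestine, y-organoid, o-organoid and crypt arrays. Outlier spots were left out of their probe's mean, and 21 probes then had no value on an array. Processed intensities were put on the log2 scale and the 75th percentile of each array was subtracted. The 75th percentile was at an intensity of 386.3 on the intestine, 281.9 on the y-organoid, 644.0 on the o-organoid and 472.3 on the crypt array, and the median was 40.5, 25.2, 36.9 and 29.5. Spots of a probe were averaged, and each gene was read by its probe with the highest mean over the arrays. Genes well above background numbered 17694 on the intestine, 16337 on the y-organoid, 16505 on the o-organoid and 15705 on the crypt array.

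Crypt was compared with intestine, each organoid with crypt, and o-organoid with y-organoid. Genes well above background on both arrays were counted as higher or lower at a difference of 4-fold (2 on the log2 scale). With 1 array per group, the number of arrays limits the precision, and differences describe arrays, not conditions. The SD of repeated spots on the log2 scale was 0.086 on the intestine, 0.096 on the y-organoid, 0.074 on the o-organoid and 0.093 on the crypt array. The count from spot noise alone was taken from 100 simulations.

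Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives but 1. The 29 lists cover stem, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, smooth muscle and pacemaker cells, stroma, enteric neurons and glia, immune cells, endothelium, and pancreas, fat and red cells. They also cover acetylcholine metabolism, muscarinic and nicotinic receptors, proliferation, Wnt ligands with R-spondins and antagonists (the Wnt ligand list), the Notch pathway, fetal-like epithelium, interferon response, antimicrobial genes, proximal small intestine, distal small intestine, colon, cholesterol synthesis, hypoxia, stress response, immediate early genes and xenobiotic metabolism. A list's median covers members well above background on at least 1 of the 2 arrays, with the dim side at its bound, and members were counted at 2-fold. Its percentile is that among 10000 random lists of the same size matched on mean signal in 20 bins. A list entered the counts of lists with at least 3 such members, which left out 1, 2, 1 and 4 lists in the 4 comparisons in the order given. Defa17, Defa20, Defa22, Defa24, Muc2 and Gsta1 were not matched to a probe here. Members matched under a current name were Defa29, Defa31 and Hbb-bt.

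The rule for named genes took, in each comparison, the 8 largest differences in each direction among annotated genes, the 3 largest bounds in each direction, up to 4 members of each list with the largest difference, and a fixed set of markers with the genes of the acetylcholine, muscarinic and nicotinic lists. List members outside this rule were named where a count of 5 or fewer took them in, and were then chosen after their values were seen: Tnfrsf19 and Atf3 for crypt and intestine, Il33 and Dnajb9 for y-organoid and crypt, and Insm1 and Neurog3 for o-organoid and y-organoid. Xist, Kdm5d and Uty were also chosen after their values were seen. Some genes taken in by the rule are not reported here.

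Alternatives were normexp background correction (offset 50) of the mean and local background intensities, quantile normalization, centring on probes above background on all arrays, the deposited value table, only probes above background on all arrays, no filter on dim probes, the mean of all probes of a gene, probes with an outlier or saturated spot on either array left out, and thresholds of 2-fold and 8-fold. Leaving out probes with an 8-base GA repeat was chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The counting was tested on simulated data with spot noise. Changed genes were drawn from those above background on both arrays with a mean signal above -2. Spot noise is small there, so which folds passed was nearly fixed in advance. The test checks the counting only, and says nothing on dim genes or on variation between samples. In a simulation of crypt against intestine over 15189 genes, 0 of 67 genes set to 3-fold, 67 of 67 set to 6-fold and 66 of 66 set to 16-fold passed 4-fold in the right direction, and 0 unchanged genes did. The same shares of changed genes passed in the other comparisons, with 1 unchanged gene called in y-organoid against crypt (14848 genes) and 0 in o-organoid against crypt (15017) and against y-organoid (15556). A raised list reached percentile 100 in each. Unchanged lists had median percentiles of 45.9, 56.1, 49.7 and 52.2 in the 4 comparisons, and 13, 11, 11 and 12 of 100 lay below percentile 5 or above percentile 95. No genome sequence was used here.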

Results

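Gene expression was measured on 1-colour Agilent arrays in 4 mouse RNA samples, with 1 array per group. The groups were whole intestine, crypt, and 2 crypt-villus organoid samples named y-organoid and o-organoid. Crypts are the epithelial pits of the gut wall that hold its stem cells, and crypt-villus organoids are epithelial structures grown in culture. What the letters y and o stand for is not given in the sources used here. The title of the series concerns acetylcholine made outside neurons and intestinal stem cells that carry Lgr5, a receptor for R-spondins. Labelling started from 40 ng of total RNA for o-organoid and from 20 ng for each other sample. Of the spots other than controls, 58.7% were well above background on the intestine array, 54.2% on the y-organoid array, 55.1% on the o-organoid array and 51.9% on the crypt array. There are no replicates, so each difference compares 2 arrays and carries no test, p-value or standard error between groups. Signals are log2 values relative to the 75th percentile of their array, and each difference is written as the array named before minus the array named after. A gene not well above background on an array has only a bound there, written as at least N-fold: its bright side was set against the higher of the dim probe's own signal and the lowest signal among probes well above background. That lowest signal was -4.48 on the intestine, -4.47 on the y-organoid, -5.01 on the o-organoid and -4.53 on the crypt array. A gene dim on both organoid arrays can thus have a larger bound against o-organoid, which does not show a lower level there. Repeated spots gave a difference between arrays a technical SD of 0.11 to 0.13, which leaves out labelling and hybridisation. Among repeated probes with signals below -2 the SD on an array was 0.307 to 0.38, so differences of dim genes are less precise. A range after a list's median spans its values over the alternative settings. Across 18466 probes, which are not independent replicates, the arrays correlated with Pearson's r between 0.888 (intestine and y-organoid) and 0.959 (intestine and crypt).

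Crypt was compared with whole intestine. Stem cell, cell cycle and immediate early transcripts were higher on the crypt array, and transcripts of muscle, connective tissue, blood vessels, immune cells and pancreas were lower. Lgr5 was 2.54-fold higher (signals -0.40 and -1.75), Ascl2, a transcription factor of crypt base stem cells, 2.71-fold, and Olfm4, a secreted stem cell marker, 2.48-fold. Of 12 stem cell markers, 7 were at least 2-fold higher and 1, Tnfrsf19 (-1.15), was lower, with a median difference of 1.19 (range 0.94 to 1.94, the lowest with normexp background correction) at percentile 100 of 10000 random lists matched on signal. Of 19 measured proliferation genes 18 were at least 2-fold higher, with a median of 1.56 (range 1.41 to 2.31) at percentile 100, led by the DNA topoisomerase Top2a (4.07-fold) and the mitotic kinase Cdk1 (3.90-fold). The proliferation marker Mki67 was 2.81-fold higher. The immediate early list had a median of 1.29 (range 1.14 to 2.04) at percentile 100, with Fosb 7.14-fold, Egr1 4.99-fold and Ier2 4.27-fold higher, whereas Atf3 was lower (-1.42).

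The widest differences between crypt and intestine were those of pancreatic digestive enzymes. Cel, a lipase, had a difference of -13.60 (12400-fold lower on the crypt array), the carboxypeptidase Cpa1 had -13.50, and the proteases Cela3a, Try4, Cela1, Ctrb1 and Ctrl lay between -12.94 and -12.11. Try5, Cela3b and Prss2 were not well above background on the crypt array and were at least 22000-, 20800- and 19200-fold lower there. Trypsin genes have close relatives, and probes were not searched for sequence shared within these enzyme families, so values of single members are uncertain. The list of pancreas, fat and red cell genes had a median of -7.94 (range -10.01 to -6.44), and all 14 members were at least 2-fold lower on the crypt array. All 12 members of the fibroblast and stroma list were lower (median -5.20, range -7.08 to -3.45), with decorin, Dcn, at least 579-fold lower and Col1a2 at least 278-fold. The smooth muscle and pacemaker list had a median of -5.00 (range -5.15 to -1.91), with 10 of 11 members at least 2-fold lower, among them Acta2 (at least 443-fold) and Actg2 (at least 433-fold). All 14 immune members were lower (median -2.87, range -3.15 to -2.12), led by the immunoglobulin joining chain Jchain (at least 1760-fold). The endothelium list had a median of -2.20 (range -2.68 to -0.98) and the enteric neuron and glia list -1.59 (range -2.58 to -0.65), with the neuropeptide gene Vip at least 10.2-fold lower. All 10 interferon response genes were lower (median -3.69, range -3.84 to -2.94), with Isg15 15.4-fold and Rsad2 21.4-fold lower. The fetal-like and regenerative list had a median of -1.91 (range -2.06 to -1.16), with clusterin, Clu, 406-fold and Ly6a 61.7-fold lower on the crypt array. Whether these transcripts came from epithelium or from other tissue in the intestine RNA was not tested.

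Enterocyte, goblet and tuft medians differed little between crypt and intestine, and those of Paneth and enteroendocrine cells were higher on the crypt array. Each of the 17 enterocyte genes differed by less than 2-fold, and the median was -0.27 at percentile 0.01; with the deposited scaling the median was 0.48. Alpi, the intestinal alkaline phosphatase, was 1.78-fold lower on the crypt array. The Paneth cell list had a median of 0.63 at percentile 99.81 (1.38 with the deposited scaling) and the enteroendocrine list 0.74 at percentile 99.92 (1.49 with that scaling), with 6 of 15 enteroendocrine members at least 2-fold higher. A further list of pan-epithelial genes had a median of 0.46 at percentile 96.89. Part of these differences may thus not be particular to Paneth or enteroendocrine cells. Stem cell and proliferation medians of this comparison were not set against the pan-epithelial list. The goblet list had a median of 0.22 (0.97 with that scaling). The tuft list had a median of -0.05, which lay between -0.20 and 0.79 over the alternative settings. Cholesterol synthesis genes had a median of 0.95 (1.70 with the deposited scaling), with Lss 3.15-fold and Cyp51 2.57-fold higher. The hypoxia and glycolysis list had a median of 0.30 (1.05 at the highest setting), the antimicrobial list -0.94 (range -1.09 to -0.19), the stress response list -0.46 (0.29 at the highest setting) and the xenobiotic list -0.26 (0.49 at the highest). Genes higher on the crypt array without regard to lists were the transcription factors Sox5 (7.20-fold) and Osr2 (6.57-fold), the histone gene H2bc8 (6.16-fold), the chaperone Hsph1 (5.77-fold), Mreg (5.63-fold), the kinetochore gene Ndc80 (a difference of 2.49) and the sphingomyelinase Enpp7 (5.34-fold). Eif2s3y, H2ac6 and Ddx3y were not well above background on the intestine array and were at least 46.8-, 11.7- and 10.8-fold higher on the crypt array; Eif2s3y and Ddx3y lie on chromosome Y. Xist, which is transcribed from the inactive X chromosome of females, was above background on the intestine array (-1.17) and on no other. The intestine RNA thus carried the sex-linked transcripts of female mice and the crypt RNA those of male mice, so the sex of the animals and the animals themselves cannot be separated from tissue in this comparison.

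Among 15198 genes measured on both arrays, 47 were at least 4-fold higher and 462 at least 4-fold lower on the crypt array. A further 18 and 877 genes had only a bound past 4-fold. Of 28 lists with at least 3 members above background, 3 had a median at least 2-fold higher and 9 at least 2-fold lower. Spot noise alone gave at most 2 genes past 4-fold in 100 simulations. Of 55 such genes with another measured probe, 48 had that probe at least 2-fold the same way and 2 had the opposite sign. The split was 563 higher and 288 lower with the deposited scaling, and 127 and 404 with quantile normalization.

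**Figure D1:**
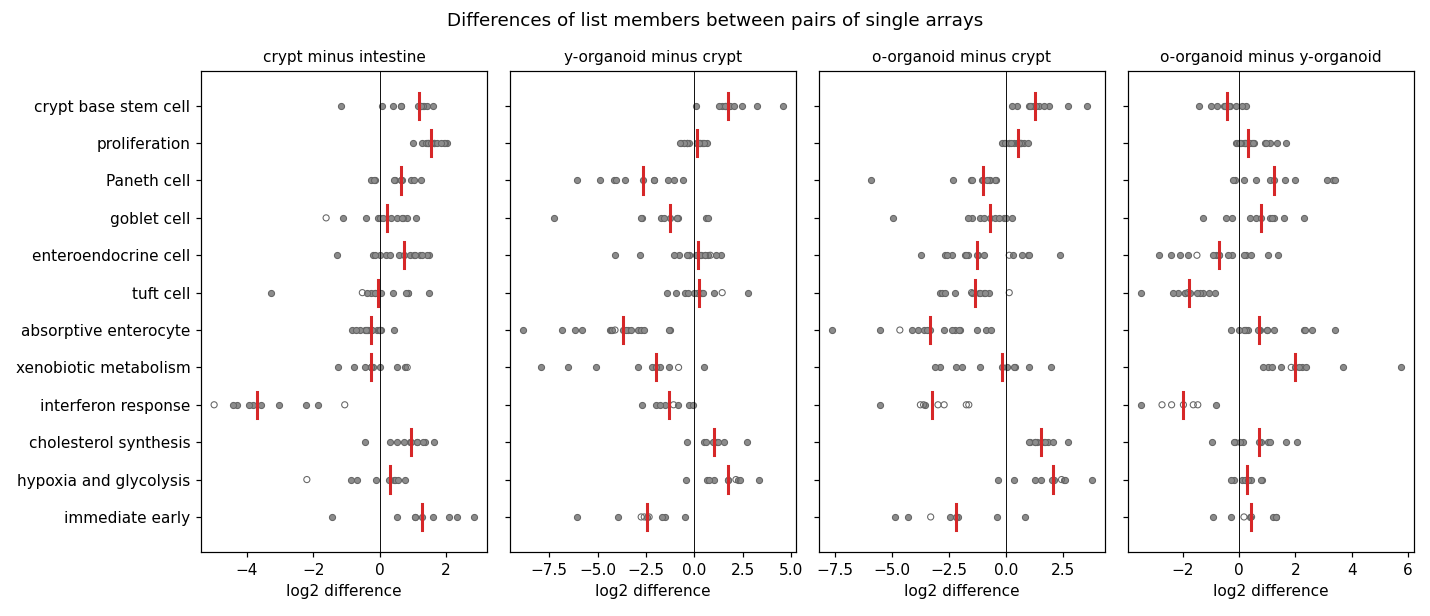
Log2 differences of the members of 12 gene lists in the 4 comparisons of single arrays, with filled points for measured members, open points for bounds and a red bar at each list's median. The stem cell median is 1.19 for crypt minus intestine, 1.71 for y-organoid minus crypt and 1.27 for o-organoid minus crypt, and the enterocyte medians of those comparisons are -0.27, -3.67 and -3.34 (0.48 for crypt minus intestine with the deposited scaling).

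The y-organoid array was compared with the crypt array. Stem cell, fetal-like, hypoxia and cholesterol transcripts were higher on the y-organoid array, and enterocyte, Paneth, goblet, xenobiotic and immediate early transcripts were lower. Lgr5 was 9.51-fold higher (signals 2.85 and -0.40), Ascl2 2.95-fold and Olfm4 2.68-fold. Of 12 stem cell markers 11 were at least 2-fold higher, with a median of 1.71 at percentile 100; Tnfrsf19 was 23.6-fold and Axin2, a target of Wnt signalling, 5.40-fold higher. The fetal-like and regenerative list had a median of 3.83 at percentile 100, with the growth factor gene Areg 81.6-fold, Ly6a 19.5-fold and Clu 18.9-fold higher, and Il33 at least 8.90-fold lower. With no filter on dim probes the list's median was 0.48, but it then covered all 12 members and not only the 8 above background on at least 1 of these arrays. With normexp the median was 2.26. Hypoxia and glycolysis genes had a median of 1.73 at percentile 100, with Ero1a 10.2-fold and Vegfa 4.83-fold higher. Cholesterol synthesis genes had a median of 1.03 at percentile 99.86, with Insig1 6.54-fold higher. That median was under 2-fold with normexp (0.81), quantile normalization (0.91) and the deposited scaling (0.52). In the stress response list (median 0.07, lowest setting -0.56), Chac1 was at least 123-fold, Trib3 10.5-fold and the asparagine synthetase gene Asns 7.37-fold higher. Of its 10 members 4 were at least 2-fold higher, 4 lay within 2-fold, and Sdf2l1 (2.52-fold) and Dnajb9 (2.34-fold) were lower.

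All 17 enterocyte genes were at least 2-fold lower on the y-organoid array (median -3.67, percentile 0). The lactase gene Lct was 460-fold lower, Rbp2, a retinol-binding protein, 116-fold, Apoa4 73.0-fold and Alpi 10.9-fold. Of 11 Paneth cell genes 10 were at least 2-fold lower (median -2.66), with Defa31 66.9-fold, Mmp7 17.6-fold and lysozyme, Lyz1, 4.33-fold lower. Alpha-defensin genes have close relatives for which probes were not searched, and their single values are uncertain. The goblet list had a median of -1.25 (range -1.76 to -0.98), with Zg16 151-fold lower. The antimicrobial lectins Reg3b, Reg3a and Reg3g were 616-, 93.8- and 24.1-fold lower, within a list median of -0.53 (range -2.27 to 0.23). The cytochrome P450 genes Cyp2b10 and Cyp3a11 were 240- and 92.5-fold lower, and the xenobiotic list had a median of -2.0. Fos was 66.9-fold and Fosb 15.7-fold lower, and the immediate early list had a median of -2.46 (range -2.97 to -1.33). The interferon list had a median of -1.29 (between -1.81 and -0.40 over the settings), with Irf7 6.54-fold lower. In the immune list (median -0.47, range -1.01 to -0.05), Cd74, the chain that escorts class II histocompatibility molecules, was 94.0-fold lower. The class II gene H2-Ab1 was 217-fold lower, and its other probe had -7.42. Slc5a11 was 134-fold and Dnase1 129-fold lower, and Apol10a, H2-Eb1 and Cubn were at least 331-, 216- and 194-fold lower.

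Proliferation genes all lay within 2-fold of the crypt array (median 0.13, lowest setting -0.39), and Mki67 differed by 0.26. The enteroendocrine list had a median of 0.17 (lowest setting -0.35), with Nts 17.2-fold and Sct 7.04-fold lower and Neurog3, which starts endocrine differentiation, 2.55-fold higher. The tuft list had a median of 0.23 (lowest setting -0.29), with Dclk1 6.80-fold higher by its brightest probe and a median of 1.20 over its other 2 probes. The endothelium list had a median of 1.26 over 6 members (lowest setting 0.58), with Egfl7 6.09-fold higher. The median was 0.38 for smooth muscle (5 members, lowest setting -0.17), -0.18 for stroma (2 members), 1.19 for neurons and glia (4 members, lowest setting 0.29) and -1.30 for pancreas, fat and red cells (5 members, range -1.83 to -0.18). Of the 8 genes with the largest positive differences, Mrgprg (98.8-fold), Gbp6 (89.0-fold), Klra1 (87.4-fold), Ddx25 (77.5-fold), Scn3b (66.7-fold) and Cd300lf (63.6-fold) were read by probes with a GA repeat. The other 2 probes of Cd300lf had a median of -1.01, and without repeat probes its difference was -0.89. The remaining 2 of these 8 were Areg and Emp2 (68.3-fold), each with 1 measured probe. Myl9, Stc2 and Chac1 were at least 223-, 153- and 123-fold higher.

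Among 14847 genes measured on both arrays, 596 were at least 4-fold higher and 588 at least 4-fold lower on the y-organoid array, and 236 and 167 more had only a bound past 4-fold. Of 27 lists with at least 3 members above background, 6 had a median at least 2-fold higher and 9 at least 2-fold lower. Of the 596 genes, 28 were read by probes with a GA repeat. Spot noise alone gave at most 3 genes. Of 209 genes past 4-fold with another measured probe, 143 had it at least 2-fold the same way and 19 had the opposite sign. The split was 291 higher and 1057 lower with the deposited scaling, and 258 and 443 with normexp background correction.

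The o-organoid array was compared with the crypt array. Stem cell, fetal-like, hypoxia and cholesterol transcripts were higher on the o-organoid array, and enterocyte, immediate early and interferon transcripts were lower. Lgr5 was 6.57-fold higher (signals 2.31 and -0.40), Ascl2 2.71-fold and Olfm4 2.13-fold, and the stem cell median was 1.27 at percentile 100. The fetal-like list had a median of 2.78 at percentile 100, with Clu 39.4-fold, Areg 9.23-fold and Anxa1 at least 25.7-fold higher. Of its 8 members above background, 6 were at least 2-fold higher and 1, Il33, was at least 12.9-fold lower. With no filter on dim probes that median was 0.99, but it then covered all 12 members and not only these 8. With normexp the median was 1.53. All 11 cholesterol synthesis genes were at least 2-fold higher (median 1.53, percentile 100), with Lss 6.53-fold and Cyp51 4.18-fold higher. The desaturase Scd1 was 35.8-fold higher. Hypoxia and glycolysis genes had a median of 2.06 at percentile 100, with Ero1a 13.5-fold and Ndrg1 5.77-fold higher. In the stress response list (median 0.57, range 0.35 to 0.69), Chac1 was at least 201-fold, Trib3 7.89-fold and Asns 5.69-fold higher, and of its 10 members 4 were at least 2-fold higher and 0 at least 2-fold lower.

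Of 17 enterocyte genes 15 were at least 2-fold lower on the o-organoid array (median -3.34, range -3.37 to -2.70, percentile 0), with Lct 197-fold, Apoa1 45.2-fold and Slc15a1, a peptide transporter, at least 24.9-fold lower, whereas Alpi was 1.81-fold lower. The Paneth list had a median of -1.02 (highest setting -0.85), with Lyz1 2.05-fold lower, and the goblet list -0.69, with Zg16 30.8-fold lower. The enteroendocrine list had a median of -1.24, with secretin, Sct, 6.32-fold and somatostatin, Sst, 6.02-fold lower and Neurog3 5.18-fold higher. The tuft list had a median of -1.34 (-0.85 with normexp), with Siglecf 7.30-fold and Alox5 6.99-fold lower. All 8 interferon genes above background on at least 1 of these arrays were at least 2-fold lower (median -3.24, range -3.59 to -1.72, with 6 of the 8 at bounds), with Isg15 45.3-fold lower. The immediate early list had a median of -2.17 (range -2.27 to -1.44), with Fos 29.0-fold lower. Reg3b was 255-fold lower, and the antimicrobial list had a median of -0.41 (lowest setting -2.20). Among class II pathway genes, Cd74 was 241-fold lower, H2-Ab1 at least 747-fold and H2-Eb1 at least 313-fold, and the immune list had a median of -1.19 (-0.70 with normexp). Psmb8, a subunit of the immunoproteasome, was 224-fold lower, Unc93a 194-fold, Apol10a 188-fold, Slc5a4a 187-fold and Apol9b 175-fold. Cubn was at least 281-fold lower.

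Proliferation genes all lay within 2-fold of the crypt array (median 0.55). The xenobiotic list had a median of -0.15, which lay between -0.64 and 0.04 over the settings, with Cyp3a25 8.60-fold lower and Gsta4 3.92-fold higher. The median was 0.04 for smooth muscle (4 members, lowest setting -0.15), -0.62 for stroma (2 members), 0.71 for neurons and glia (6 members, lowest setting -0.56), 0.27 for endothelium (6 members, lowest setting -0.34) and -1.18 for pancreas, fat and red cells (5 members, highest setting -0.71). Pip5k1a was 57.6-fold higher by its brightest probe, while its other 2 probes had a median of -0.03. Acta1 was 44.0-fold, Emp2 38.3-fold, the carbonyl reductase Cbr3 28.7-fold and Rgcc 24.5-fold higher, and Mt4 and Stc2 at least 363- and 138-fold.

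Among 15012 genes measured on both arrays, 227 were at least 4-fold higher and 566 at least 4-fold lower on the o-organoid array, and 78 and 188 more had only a bound past 4-fold. Of 28 lists with at least 3 members above background, 4 had a median at least 2-fold higher and 10 at least 2-fold lower. Spot noise alone gave at most 1 gene. Of 117 genes past 4-fold with another measured probe, 98 had it at least 2-fold the same way and 7 had the opposite sign. The split was 127 higher and 397 lower with normexp background correction. Of 14656 genes measured on the crypt and both organoid arrays, 594 were at least 4-fold higher than crypt on the y-organoid array and 227 on the o-organoid array, and 148 on both. Independent lists of these sizes would share 9.2. Of the 568 and 514 genes at least 4-fold lower, 329 were shared, against 19.9 for independent lists. The differences from crypt correlated across genes with r of 0.66, and their covariance was 0.77. Simulations of unchanged arrays gave an overlap of at most 1, an r of 0.56 and a covariance of 0.0335, but they hold spot noise only, without labelling, hybridisation or animals, and so understate what 2 unchanged samples would share. Both comparisons share the crypt array, which cannot be split, so part of the excess may come from that array.

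The o-organoid array was compared with the y-organoid array. Xenobiotic, Paneth and some enterocyte transcripts were higher on the o-organoid array, and tuft, interferon and several endocrine transcripts were lower. Of 11 xenobiotic genes 10 were at least 2-fold higher (median 1.99, range 1.66 to 2.63, percentile 100), with Cyp2b10 53.2-fold and Cyp3a11 12.8-fold higher. Cyp2c38 was 46.0-fold higher, the glucuronosyltransferase genes Ugt2b5 and Ugt2b36 21.9- and 20.0-fold, and the retinaldehyde dehydrogenase Aldh1a1 13.3-fold. Members of these enzyme families are similar in sequence, so single values are uncertain. The transporters Slc5a4b and Slc6a19 were 16.4- and 11.1-fold higher, and Cyp3a16, Aqp3 and Cyp2b9 at least 12.9-, 9.21- and 8.15-fold. The Paneth list had a median of 1.23 (range 1.23 to 1.87) at percentile 100, with Defa26 10.5-fold, Mmp7 8.68-fold and Lyz1 2.11-fold higher. The enterocyte list had a median of 0.72 (1.36 with the deposited scaling), with Rbp2 (a difference of 3.42) and Alpi (6.03-fold) higher, and the goblet list 0.76 (1.39 with that scaling), with Zg16 4.91-fold higher. Clca1 was 2.47-fold lower by its brightest probe but had a difference of 0.17 as a mean of all its probes.

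Of 12 tuft genes 11 were at least 2-fold lower on the o-organoid array (median -1.78, range -1.88 to -1.14, percentile 0), with Trpm5, a cation channel, 4.54-fold lower. Dclk1 was 11.3-fold lower by its brightest probe, which gave a larger difference than its other probes for y-organoid against crypt. The enteroendocrine list had a median of -0.70 (range -0.70 to -0.06), with Sst 7.23-fold, glucagon, Gcg, 5.33-fold and Cck 4.33-fold lower, and the precursor genes Insm1 and Neurog3 higher (1.39 and 1.02). The interferon list had a median of -1.98 (range -2.75 to -1.26), with Isg15 11.2-fold lower. Lgr5 differed by -0.53, Ascl2 by -0.12 and Olfm4 by -0.33, and the stem cell median was -0.43 at percentile 5.53 (0.20 at the highest setting). The fetal-like list had a median of 0.50, between -0.78 and 1.14 over the settings, with Areg 8.84-fold lower and Sprr1a 3.89-fold higher. The median was 0.33 for proliferation (range 0.28 to 0.96), 0.71 for cholesterol synthesis (range 0.42 to 1.35), 0.27 for hypoxia and glycolysis (range 0.24 to 0.90), 0.12 for stress response (range 0.11 to 0.76), -0.69 for immune cells (range -0.76 to -0.05) and -1.05 for endothelium (highest setting -0.41). It was 0.41 for immediate early genes (range 0.08 to 1.05), among which Fos was 2.30-fold higher but had -0.01 with normexp background correction. It was 0.35 for the antimicrobial list (range -0.48 to 0.99), -0.74 for smooth muscle (highest setting 0.02) and -0.91 for neurons and glia (range -0.92 to -0.05). The stroma list had 1 measured member, at -0.35, and the pancreas, fat and red cell list 2, with a median of 1.49.

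Of the 8 genes with the largest negative differences, Klra1 (177-fold lower), Ddx25 (170-fold), Tbx22 (150-fold), Gbp6 (145-fold), Scn3b (135-fold), Cd300lf (131-fold) and Tdgf1 (96.9-fold) were read by probes with a GA repeat, as were Mrgprg, Syn3 and Rhox3a (at least 220-, 112- and 41.5-fold lower). The remaining gene, Myl9, was 84.3-fold lower. Among 15549 genes measured on both arrays, 136 were at least 4-fold higher and 387 at least 4-fold lower on the o-organoid array, and 28 and 136 more had only a bound past 4-fold. Of the 387 genes, 24 were read by repeat probes. Of 25 lists with at least 3 members above background, 2 had a median at least 2-fold higher and 5 at least 2-fold lower. The lower ones were the tuft (percentile 0), interferon (0.01), endothelium (2.85), Wnt ligand (11.18) and nicotinic (14.34) lists. Wnt ligand and nicotinic medians were thus not unusual among matched random lists. Spot noise alone gave at most 1 gene. Of 78 genes past 4-fold with another measured probe, 50 had it at least 2-fold the same way and 4 had the opposite sign. The split was 556 higher and 125 lower with the deposited scaling, 74 and 124 with normexp and 177 and 278 with quantile normalization. The RNA input differed between these arrays, 40 ng for o-organoid and 20 ng for y-organoid, and the effect of input cannot be separated from that of the sample.

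The genes of acetylcholine signalling were described on each array, since the title of the series concerns this transmitter. Chat, which makes acetylcholine, was not well above background on any of the 4 arrays, nor were the choline transporter gene Slc5a7, Slc44a5, Slc22a2, Slc22a3 or Prima1. Such a call does not show that a transcript was absent. The intestine array read the enteric neuron genes Vip (-1.18) and Prph (-1.28), and Slc18a3, yet not Chat. Whether the Chat probe can read its transcript was not tested, so its calls say little on crypt or organoids. Bche, which breaks down choline esters, was above background on all 4, with signals of 3.59 on the intestine, 3.98 on the crypt, 2.90 on the y-organoid and 3.25 on the o-organoid array. Ache, which breaks down acetylcholine, was above background on the intestine (-4.23) and y-organoid (-4.05) arrays. Slc18a3, the vesicular acetylcholine transporter, was above background on the intestine (-2.59), y-organoid (-3.53) and o-organoid (-4.59) arrays. On the crypt array its signal was -4.45 and not well above background, so the calls show no difference between crypt and o-organoid. The choline transporter-like genes Slc44a1 to Slc44a4 were above background on all arrays. Slc44a2 was 3.90-fold and Slc44a1 2.95-fold higher on the y-organoid than on the crypt array, although the other 3 probes of Slc44a1 had a median of 0.70. Crat, a carnitine acetyltransferase, was at least 6.30-fold lower on the y-organoid than on the crypt array. The list of 16 genes had medians of 0.11 for crypt minus intestine (range -0.04 to 0.98), -0.09 for y-organoid minus crypt (between -1.10 and 0.44), -0.69 for o-organoid minus crypt and 0.35 for o-organoid minus y-organoid (range -0.89 to 0.99).

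Of the muscarinic receptors, Chrm3 was above background only on the organoid arrays, at -1.50 on the y-organoid and -2.34 on the o-organoid array, at least 8.20- and 4.58-fold above crypt. Chrm1 was above background only on the crypt array (-2.95), at least 2.88-fold above y-organoid and 4.17-fold above o-organoid. These bounds differ only because the lowest signal well above background was -4.47 on the y-organoid and -5.01 on the o-organoid array. Chrm4 was above background on the intestine (-4.09) and o-organoid (-3.83) arrays, and Chrm2 and Chrm5 on no array. The muscarinic medians were 0.50, 0.76, 0.70 and -0.25 for crypt minus intestine, y-organoid minus crypt, o-organoid minus crypt (lowest setting -0.21) and o-organoid minus y-organoid, over 2 or 3 members with mostly bounds. Of the nicotinic subunits, Chrna2 and Chrna4 were above background on all 4 arrays, with signals of -2.15 and -2.59 on the y-organoid and -2.83 and -3.95 on the o-organoid array. Chrna10 was 2.05-fold higher on the crypt than on the intestine array and at least 5.96-fold lower on the o-organoid than on the crypt array. Chrna9, Chrnb1, Chrnb2 and Chrnb4 were above background on some arrays, and the other 9 of the 16 subunits on none. The nicotinic medians were -0.11 for crypt minus intestine (percentile 71.04, highest setting 0.64) and 0.36 for y-organoid minus crypt (percentile 31.21, lowest setting -0.16). They were -0.78 for o-organoid minus crypt (percentile 8.33) and -1.16 for o-organoid minus y-organoid (percentile 14.34, highest setting -0.46). Most of these signals were below -2, where repeated spots vary most. In mm9 coordinates of the files, the probe of Lgr5 lies on chromosome 10 at 114887403 to 114887462, of Bche on chromosome 3 at 73439735 to 73439794, of Chrm3 on chromosome 13 at 9875880 to 9875939, of Chrm1 on chromosome 19 at 8758011 to 8758070 and of Chat on chromosome 14 at 33221421 to 33221480. Exon and untranslated region annotation of that build was not used here.

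**Figure D2:**
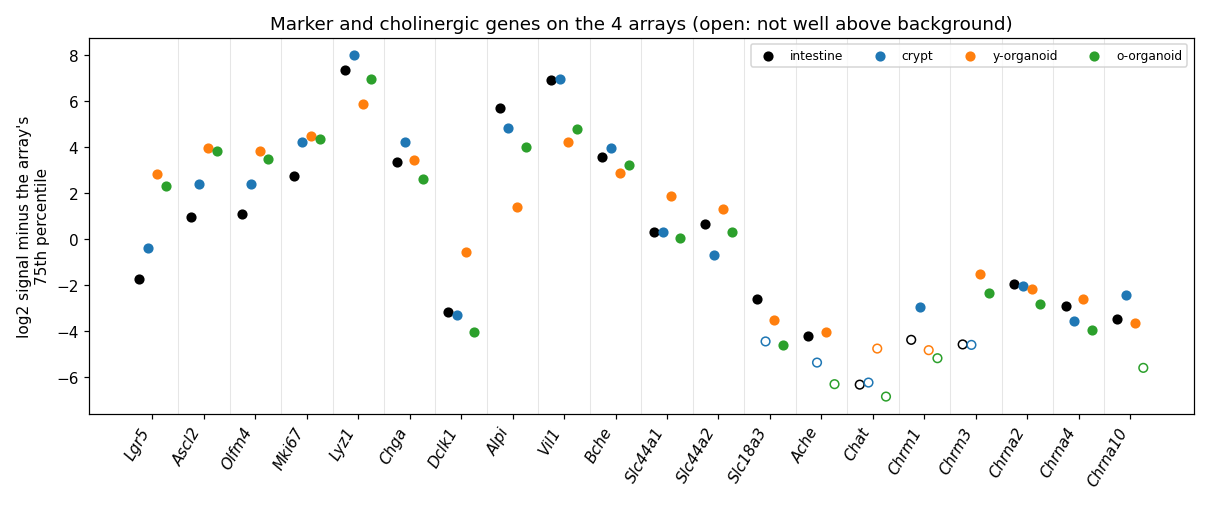
Signals of 20 marker and cholinergic genes on the 4 arrays, as log2 values minus the 75th percentile of each array, with open points where a probe was not well above background. Lgr5 lies at -1.75 on the intestine array, -0.40 on the crypt array, 2.85 on the y-organoid array and 2.31 on the o-organoid array, and Chat is open on all 4.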

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

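In 4 of the 29 gene lists the organoids' median differences from crypt had opposite signs. The enteroendocrine list had a median of 0.17 (percentile 76.87) for y-organoid minus crypt and -1.24 (percentile 0) for o-organoid minus crypt. The tuft list had 0.23 (39.88) and -1.34 (0.01), and the nicotinic receptor list 0.36 (31.21) and -0.78 (8.33). The Wnt ligand list had 0.82 (73.39) and -0.04 (51.69). All y-organoid medians here, and the o-organoid median of the Wnt ligand list, lay between percentiles 31.21 and 76.87 of matched random lists. Their signs alone do not set them apart from such lists. These differences between organoids were not tested, since each rests on single arrays, and both share the crypt array. The y-organoid medians of the first 3 lists turned negative under some settings: the enteroendocrine list to -0.35 with the deposited value table and -0.27 without probes that had an outlier spot, the tuft list to -0.29 with the deposited table and -0.17 with quantile normalization, and the nicotinic list to -0.16 and -0.09 with those settings. The o-organoid median of the Wnt ligand list turned positive, at 0.08 with the deposited table and 0.07 with quantile normalization.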

How the results depend on the processing

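Counts that moved by over 1.5 times are given as genes higher and lower at 4-fold and lists higher and lower at 2-fold; counts not printed stayed within 1.5 times. The cause of each shift was not tested unless stated. With normexp, crypt against intestine gave 29 genes higher and 285 lower, y-organoid against crypt 258 higher with 3 lists higher and 5 lower, o-organoid against crypt 127 higher with 5 lists lower, and o-organoid against y-organoid 74 higher and 124 lower with 3 lists lower. With quantile normalization, crypt against intestine gave 127 higher, and o-organoid against y-organoid 2 lists lower. With the deposited value table, which scales by the median, crypt against intestine gave 563 higher and 288 lower with 9 lists higher, y-organoid against crypt 291 and 1057 with 3 lists higher, and o-organoid against y-organoid 556 and 125 with 7 lists higher and 2 lower. That table shifted the median of all genes by 0.75, -0.52, 0.12 and 0.64 for crypt minus intestine, y-organoid minus crypt, o-organoid minus crypt and o-organoid minus y-organoid. Quantile normalization shifted the last by 0.15 and centring the crypt minus intestine median by -0.15. With only probes above background on all arrays, which leaves fewer members, 4 lists were lower for crypt against intestine and 2 for o-organoid against y-organoid. With no filter on dim probes, which adds genes, the counts were 207 and 2146 for crypt against intestine, 1461 and 965 with 3 lists higher for y-organoid against crypt, 527 and 1139 for o-organoid against crypt, and 238 and 1130 with 2 lists lower for o-organoid against y-organoid. At 2-fold the counts, in that order of comparisons, were 1097 and 1167, 2391 and 1969, 1200 and 1823, and 1275 and 2633. At 8-fold they were 12 and 248, 163 and 238, 67 and 208, and 23 and 65.

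Of named genes and list medians with a difference of at least 2-fold, 4 changed sign. Sign changes of list medians under 2-fold are given beside those medians. The colon list for y-organoid minus crypt went from -1.97 to 0.22 with no filter on dim probes. Cd300lf for y-organoid minus crypt went from 5.99 to -0.89 without GA-repeat probes, a setting chosen after seeing the data, because another of its probes was then read. Clca1 for o-organoid minus y-organoid went from -1.30 to 0.17 as a mean of all probes, because its probes differ. Fos for o-organoid minus y-organoid went from 1.20 to -0.01 with normexp. Values moved by more than the technical SD, or counts by over 1.5 times, without a sign change of that kind in 608 cases with the deposited table, 467 with normexp, 443 with quantile normalization, 173 with centring, 147 with no filter, 55 with the mean of probes, 25 with probes above background on all arrays, 2 without probes that had an outlier spot and 2 without GA-repeat probes. Signal over background limits dim genes most, since the SD of repeated spots was 0.307 to 0.38 at signals below -2 and 0.043 to 0.051 at signals of 4 or more.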

Other observations

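Tests chosen only after the result was seen were those of the GA repeat, of expression of the named genes for both kinds of probe, of a stain, of lost absorptive epithelium and of scaling; those of carried-over pancreas and of dilution were written before.

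The signalling and regional lists were also compared between arrays. The list of Wnt ligands, R-spondins and antagonists had a median of -2.89 (range over the settings -3.04 to -1.27) for crypt minus intestine. Dkk3 was at least 43.1-fold and Rspo1 at least 10.6-fold lower on the crypt array. Wnt4 was 15.1-fold lower there by its brightest probe and had a difference of -2.06 by its other measured probe. The list's medians were 0.82 for y-organoid minus crypt (lowest setting 0.22) and -0.04 for o-organoid minus crypt (range -0.57 to 0.08). For o-organoid minus y-organoid the median was -1.31 (percentile 11.18, highest setting -0.61), with Wnt3 at least 4.92-fold higher and Wnt4 4.06-fold lower. The Notch pathway list had medians of 0.28 (range 0.07 to 1.02), 0.03 (lowest setting -0.49), 0.02 (lowest setting -0.06) and -0.13 (highest setting 0.51) in these comparisons, with Hes5 3.19-fold higher on the y-organoid than on the crypt array. The proximal small intestine list had medians of -0.85 (range -1.0 to -0.10), 0.87 (lowest setting 0.35), 0.31 (range 0.26 to 0.48) and -0.32 (highest setting 0.32), with Cybrd1, an iron reductase, 18.7-fold higher on the y-organoid than on the crypt array. The distal list had medians of 0.74 (range 0.13 to 1.49), -1.96 (highest setting -0.74), -1.62 (highest setting -0.75) and 0.59 (2 members in the last), with Osr2 at least 8.88-fold lower on the y-organoid and at least 14.5-fold lower on the o-organoid array. The colon list had medians of -0.13 (highest setting 0.62), -1.97 (0.22 with no filter on dim probes), -2.53 (highest setting -0.67) and -0.56 (highest setting 0.19), and Aqp8, a water channel, was at least 190-fold lower on the y-organoid than on the crypt array.

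Against whole intestine, Lgr5 was 24.2-fold higher on the y-organoid and 16.7-fold higher on the o-organoid array. The stem cell medians were 2.88 and 2.41, those of cholesterol synthesis 1.77 and 2.22, and those of enterocytes -4.25 and -3.42. These 2 comparisons were not recomputed under other settings. Of sex-linked genes, Xist had a signal of -1.17 on the intestine array and was not well above background on the others. Eif2s3y had 1.28 on the y-organoid, 0.86 on the o-organoid and 1.07 on the crypt array, and Ddx3y 0.08, -0.48 and -1.05, while both were not well above background on the intestine array. Kdm5d was above background on the y-organoid array (-3.77), and Uty on the y-organoid (-3.17) and o-organoid (-4.0) arrays. The intestine RNA thus carried the sex-linked transcripts of female mice and the other 3 RNA samples those of male mice, so sex cannot be separated from sample in any comparison with intestine.

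On the y-organoid array, 222 probes were at least 4-fold brighter than on each other array, and 41 of them (18.5%) carried a GA repeat of 8 bases, against 0.41% of all probes; the 162 repeat probes had a median signal of -0.41 on the y-organoid array and of -2.53, -2.64 and -2.62 on the intestine, o-organoid and crypt arrays. Expression of the genes named for repeat-carrying probes is argued against: 0.0% of 23 such genes had another probe without the repeat that was 4-fold brighter too. For the 181 probes lacking the repeat, expression read alike by all probes of a gene is argued against as the cause of the whole set: 7 of 87 with another probe (8.0%, exact 95% interval 3.3 to 15.9) had it 4-fold brighter too, against 35.7% of intestine probes weighted to the same sizes of difference. A stain is argued against by the 8.3% of the 222 probes in the fullest of 16 blocks. Cross-hybridisation of a GA-repeat sequence may account for the repeat probes. As a cause of the whole set of 222 it cannot be told apart from others, because the share of 18.5% lies under the 30% set for it. That bound covers all 222 probes and does not test the 41 repeat-carrying probes alone, for which other causes were not separated. Smaller or transcript-specific changes stay open for the other 181, whose genes' other probes had a median difference of 0.64 to the highest other array.

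Pancreatic enzyme transcripts were far higher on the intestine than on the crypt array, with crypt minus intestine differences of -13.60 for Cel and -13.50 for Cpa1. Lost absorptive epithelium is argued against as the source, since the enterocyte list differed by only -0.27 between crypt and intestine. Carried-over pancreas may be the source: all 12 genes of a second acinar list were above background on the intestine array, with a median of -7.03 for crypt minus intestine, and 1 islet hormone was above background there alone. It cannot be told apart from other sources by the test set in advance. In that test 5 of the 12 (41.7%) were above background on the intestine array alone, between the bounds of 20% and 50%. The other 7 were also seen on another array, and the share counts such a call whatever its level. All 12 were at least 2-fold lower on the crypt and y-organoid arrays than on the intestine array, and 11 of them on the o-organoid array. The islet list had a median of -4.0, and for y-organoid minus crypt, o-organoid minus crypt and o-organoid minus y-organoid the acinar list had 0.29, -0.22 and 1.40 and the islet list 0.38, 0.06 and -0.49.

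Enterocyte transcripts were about as high on the crypt as on the intestine array, with a median difference of -0.27. Under 4 other settings it was -0.43, -0.23, -0.20 and 0.48, but this decides nothing about scaling, since the largest drop of all genes among them was -0.15, with centring, too little to bring the list to -1. Dilution of epithelium by other tissue in the intestine RNA may hide a lower level in crypt, but it cannot be told apart from other causes: relative to a pan-epithelial list, at 0.46, the enterocyte median was -0.73, between the -0.5 and -1 set in advance. The pan-epithelial list had -0.46, -0.31 and 0.01 for y-organoid minus crypt, o-organoid minus crypt and o-organoid minus y-organoid. Villus epithelium in the crypt preparation was not tested.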
